A study of Homo sapiens with 4 samples.

How the data were processed

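Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) was done on C4-2B cells, an androgen-independent prostate cancer line derived from LNCaP, with an antibody against 5-methylcytosine. Per the labels, 4 libraries were made from untreated cells harvested 48 h after plating at about 70% confluency. They were an input library and an immunoprecipitated library from cells with a control guide RNA, and the same pair from cells with a guide against PKCλ/ι, the atypical protein kinase C encoded by PRKCI. Each of the 4 groups held 1 library, and the 2 genotypes were compared through 1 peak list each.

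Reads were aligned with BWA to hg19, quality was checked with FastQC and peaks were called with MACS2, per the submitters' processing notes. Versions, parameters and duplicate handling were not given in the sources used here. The deposited lists were called per library and give for each peak its position, length, summit and 4 values. The pileup signal at the summit is a whole number of overlapping fragments that the authors did not scale between libraries. The authors' fold enrichment is the ratio of that pileup to a local background, with 1 added to each. The deposited −log10 p and −log10 q values come from the caller, and the lowest −log10 q was 2.01 in the control list and 2.00 in the knockout list. Positions are in hg19 and counted from 1, since end minus start plus 1 equalled the listed length in every peak of both lists. Lists were matched to samples by the genotype and antibody words of their names.

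The depth of the libraries was not listed, so relative depth was taken from the lists. The local background of each peak was recomputed as the pileup plus 1, divided by the authors' fold enrichment, minus 1. With this background the Poisson upper tail gave the listed −log10 p with a largest difference of 0.000573 in the control list and 0.000329 in the knockout list. The lowest background, called the floor here, is the genome-wide mean pileup in this caller's model. It was 2.92 in the control and 4.42 in the knockout, a ratio of 1.51. The 6 commonest backgrounds above the floor fell on multiples of 0.371 in the control and 0.942 in the knockout, taken as the scale from input to immunoprecipitated tags. Other backgrounds above the floor did not all fall on these multiples. In this caller's model a background above the floor comes from the input, and one at the floor from the immunoprecipitate's own mean. By these steps the input held 2.70 times the tags of the immunoprecipitate in the control and 1.06 times in the knockout.

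Peaks sharing at least 1 bp were called shared, with 100 random placements within chromosomes as the reference. Strong peaks had −log10 q of at least 10, and a list-only peak overlapped no peak of the other list at any q. For the depth-matched comparison, knockout pileups were thinned binomially by the ratio of floors and backgrounds were scaled by it. Significance was recomputed, −log10 q was taken from the control list's own relation of p to q, and the thinned list was shortened to the control list's number of peaks. This was drawn 20 times. Only summits were thinned, and the width a peak needs was not modelled. The inputs, of which the control's held 1.67 times the tags of the knockout's, could not be matched. As a no-change reference, pileups were simulated 20 times with every region at 1 level in both genotypes, with backgrounds as listed or, for regions in 1 list, taken from pairs of like background. This simulation held counting error only, with no further variation between libraries and no shift of summits. Peaks overlapping exactly 1 peak of the other list, in both directions, formed pairs. The log2 ratio of their pileups, knockout over control, was scaled by the floors because no tag totals were listed. For each of 23 chromosomes the single change point that most reduced the squared error of these ratios was located, with 100 bootstrap resamples for chromosome 3 and 100 permutations of blocks of 50 consecutive pairs on each chromosome. Runs of consecutive list-only peaks were compared with 100 permutations within chromosome and −log10 q bin, for the deposited lists and for 5 depth-matched draws.

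Intervals are at the 95% level. They are exact Poisson intervals for counts, exact Clopper-Pearson intervals for shares and ratios of counts, order-statistic intervals for medians over pairs, and a normal approximation for the difference of medians on chromosome 3. Intervals of counts and shares cover counting error only, and those over pairs cover the scatter of pairs within these libraries, not replicate error. With 1 library per group no test between genotypes was made and no p-value is given. The authors' fold and −log10 q were used to describe, rank or filter peaks within their own list. Runs, change points, the distal stretch of chromosome 3, 5 Mb bins and mitochondrial peaks were named outside any rule fixed beforehand. The other regions named were fixed by rule before the data were examined. They are the 10 strong peaks per direction with the highest fold and no peak of the other list within 1000 bp, and the 5 windows of 1 Mb per direction with the largest excess of list-only strong peaks. Alternatives varied the overlap rule, the peak thresholds, the chromosomes, the number of peaks, the depth and the scaling.

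The gene table at hand was of assembly GRCh38.p14, another build than the lists, so no peak was assigned to a gene. Promoters, gene lists and the PRKCI locus itself were not analysed here, and the knockout could not be checked from these lists. Overlap, pairing, thinning and change-point steps were tested on simulated data. All 200 peaks moved away were found as list-only among 261657, the median of 200 peaks raised by a log2 ratio of 1 came out at 0.99, and a step of -0.30 placed among 13000 pairs came out at -0.30. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.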

Results

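DNA methylation was profiled by MeDIP-seq in C4-2B prostate cancer cells with a control guide RNA and in cells knocked out for PKCλ/ι. The series set the loss of this kinase beside serine and one-carbon metabolism, the route that supplies methyl groups for DNA methylation. The comparison asks whether methylated regions differ between knockout and control cells. Each genotype had 1 input library and 1 immunoprecipitated library, so no difference reported here has a replicate check. The knockout immunoprecipitate was deeper than the control one by 1.51 times, judged by the genome-wide mean pileup of 4.42 against 2.92.

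Methylated regions were numerous and similar in size in both genotypes. The control list held 261657 peaks covering 150.7 Mb, and the knockout list held 296521 peaks covering 177 Mb. The knockout thus had 1.13 times the peaks and 1.17 times the covered length. Peaks had a median length of 458 bp in the control (quartiles 361 and 641) and 464 bp in the knockout (quartiles 366 and 657). The median pileup was 25 in the control and 36 in the knockout. Relative to each library's mean, these medians were 8.55 in the control and 8.14 in the knockout. Median fold enrichment was 5.48 in the control and 5.35 in the knockout. Strong peaks numbered 149184 in the control (57.0% of the list) and 220853 in the knockout (74.5%). With the knockout immunoprecipitate thinned to the control's depth, its strong peaks numbered 149620 on average, close to the control.

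The same chromosomes were dense in methylated regions in both genotypes. Chromosome 22 held 235 peaks per Mb in the control and 253 in the knockout. Chromosome 17 followed with 199 in the control and 216 in the knockout, and chromosome 19 with 189 and 205. Chromosome X was sparse at 29.9 peaks per Mb in the control and 37.8 in the knockout, and among the autosomes chromosome 4 was lowest at 44.8 and 55.3.

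Most methylated regions of the control cells were also found in the knockout cells. Of the control peaks 87.9% (87.8 to 88.1) overlapped a knockout peak, against 12.8% on average when peaks were placed at random. Of the knockout peaks 76.1% (75.9 to 76.2) overlapped a control peak, against 11.4% at random. These shares depended on depth and on the number of peaks. In the depth-matched comparison, with the knockout list shortened to the control's number of peaks, they were 81.8% and 79.7%. Peaks found in the control list only numbered 31568 and had a median pileup of 19, against 26 for shared peaks. Those found in the knockout list only numbered 70955, with a median pileup of 27 against 40 for shared peaks. List-only peaks were also shorter, with medians of 340 bp in the control and 353 bp in the knockout against 482 and 517 bp for shared peaks.

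Strong methylated regions missing from the other genotype were more numerous in the knockout. The excess was smaller once depth and the number of peaks were matched. In the deposited lists 32804 strong peaks (32450 to 33161) were found in the knockout only, 14.9% of its strong peaks. In the control only there were 4835 (4700 to 4973), or 3.24%. The ratio of the counts was 6.78 (6.58 to 6.99). The knockout immunoprecipitate was then thinned to the control's depth and its list shortened to the control's number of peaks. The mean counts were 11471 knockout-only and 8580 control-only peaks, and the ratio was 1.34. Equal numbers of peaks without thinning gave 7870 control-only peaks and a ratio of 4.17. At −log10 q of at least 20 the ratio was 31.9 in the deposited lists. With the same matching, 695 of 53541 knockout peaks (1.30%) and 196 of 48307 control peaks (0.406%) lacked a counterpart, a ratio of 3.55. Over the 20 draws that ratio ranged from 3.25 to 3.94, and counting error gave 3.02 to 4.18. It was 1.97 at a −log10 q of 15, 5.28 at 25 and 6.66 at 30. Where no peak of the other list was allowed within 1000 bp, 372.5 knockout-only and 149 control-only peaks were left at a −log10 q of 20, a ratio of 2.50. At that strength the ratio was 5.06 without peaks whose background exceeded 5 times the floor, and 3.92 without chromosomes 2 and 3. A simulation with every region at 1 level in both genotypes gave a mean of 14.6 knockout-only and 22.7 control-only peaks at that strength, a ratio of 0.641, and the simulated ratio was 0.763 at 10, 0.627 at 15, 1.15 at 25 and 2.45 at 30. It held counting error only and gave far fewer list-only peaks than were observed in either genotype. The inputs were not matched, and the control input held 1.67 times the tags of the knockout input.

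**Figure D1:**
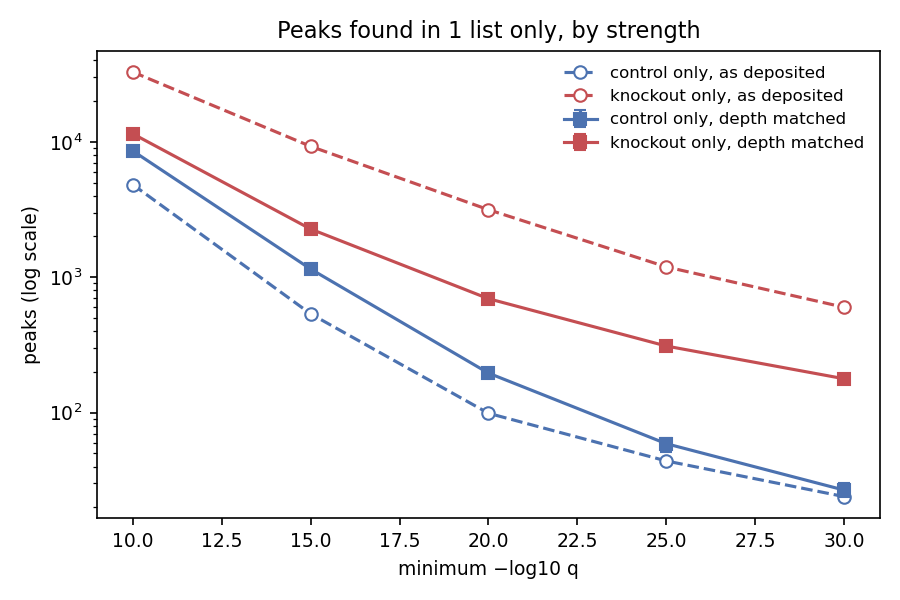
Number of peaks with no overlapping peak in the other list (log axis) against the minimum −log10 q, for control and knockout lists as deposited (open circles, dashed) and depth matched (filled squares, mean of 20 draws, with bars for the range of draws, mostly smaller than the symbols). At a minimum of 20 the depth-matched counts were 695 in the knockout and 196 in the control.

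The strongest regions found in knockout cells only lay on chromosomes 1, 2, 4, 6, 9, 10 and 19. The most enriched was on chromosome 10 at 89114431 to 89115433, with a pileup of 93 (75.1 to 114), 21.0 times the library mean, and a fold of 17.3. Chromosome 4 at 78034222 to 78034724 had a pileup of 81 and a fold of 14.9. Chromosome 1 at 235105484 to 235106148 had a pileup of 82 and a fold of 14.5. Chromosome 4 at 116599428 to 116600254 had a pileup of 86 and a fold of 13.7, and chromosome 9 at 131872271 to 131873032 had the highest pileup of the 10, 103 (84.1 to 125). The other 5 lay on chromosome 10 at 27638802, chromosome 9 at 123398800, chromosome 19 at 46404394, chromosome 2 at 130763325 and chromosome 6 at 168366263. Over all 10 the fold ran from 13.1 to 17.3. The control list held peaks with a pileup as low as 10 where the background was at its floor, and it listed none within 1000 bp of these regions.

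The strongest regions found in control cells only lay on chromosomes 1, 2, 3, 10, 12, 17 and 22. The most enriched was on chromosome 17 at 874570 to 876281, with a pileup of 42 (30.3 to 56.8), 14.4 times the library mean, and a fold of 10.5. Chromosome 10 at 8150287 to 8150702 had a pileup of 39 and a fold of 10.2, and chromosome 1 at 150748346 to 150748821 had a pileup of 39 and a fold of 9.99. Of the other 7, 3 lay on chromosome 2 (starting at 77606274, 15012666 and 19877848), 2 on chromosome 22 (32825059 and 47103226), 1 on chromosome 12 (75469942) and 1 on chromosome 3 (183215557), inside a distal stretch from 169.9 Mb where the knockout had lower pileup and background in general. Over all 10 the fold ran from 8.90 to 10.5. The knockout list held peaks with a pileup as low as 14 at its floor and none within 1000 bp of these regions.

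Knockout-only strong peaks were spread over the genome. Of 2774 windows of 1 Mb with any list-only strong peak, 2621 held more knockout-only and 93 more control-only peaks. The largest knockout excess was on chromosome 19 at 47 to 48 Mb and on chromosome 3 at 32 to 33 Mb, each with 46 knockout-only peaks against 1 control-only peak. Chromosome 17 at 19 to 20 Mb held 44 against 1, and chromosome 19 at 45 to 46 and at 49 to 50 Mb held 43 against 1 each. These windows were dense in peaks, with 300, 238, 333, 280 and 385 knockout peaks of any strength, in the order named. The knockout mean per Mb was 205 on chromosome 19, 93.9 on chromosome 3 and 216 on chromosome 17. The excess is a count and was not taken relative to the peaks in a window. By chromosome, the knockout-only share of strong knockout peaks was highest on X at 22.4% and chromosome 4 at 20.9%, leaving out the few peaks of Y. It was lowest on chromosome 22 at 10.5% and chromosome 19 at 10.9%. Peaks were weak on X (median pileup 20 in the control and 27 in the knockout) and on chromosome 4 (22 and 32). They were stronger on chromosome 22 (26 and 40) and chromosome 19 (26 and 39). Chromosome 2, with 22 and 31, had a share of only 14.4%. Whether weak peaks missing the threshold in the shallower control list set this order was not tested. These window and chromosome counts are from the lists as deposited, at unequal depth.

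**Figure D2:**
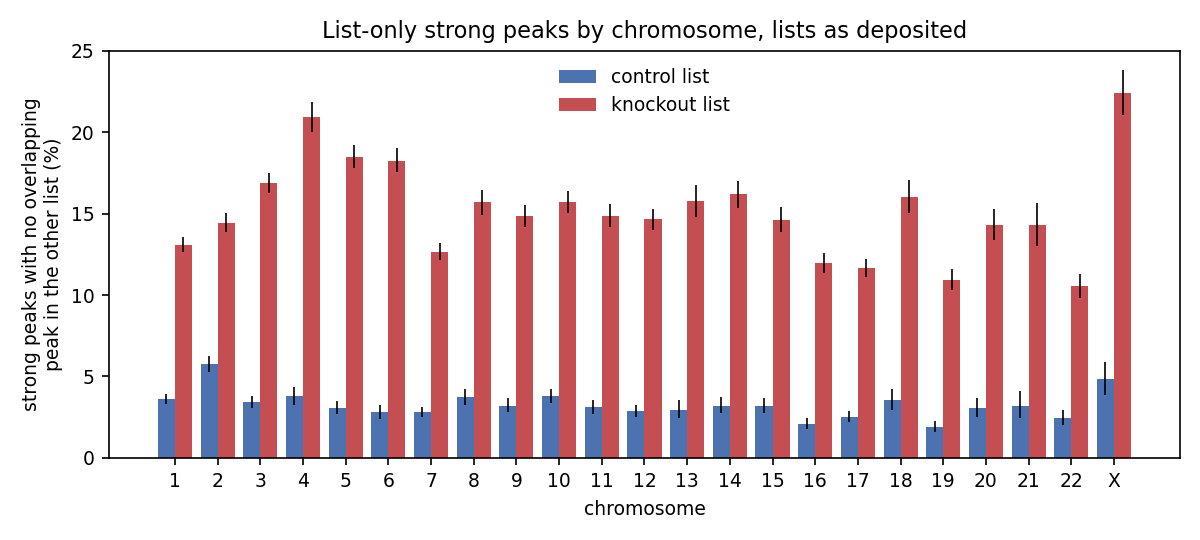
Share of strong peaks with no overlapping peak in the other list, in percent, by chromosome for the control list and the knockout list, with exact 95% binomial intervals for counting error (Y not drawn). The knockout share was highest on X at 22.4%, and the control share was highest on chromosome 2 among the autosomes, at 5.74%.

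Few windows held more control-only than knockout-only strong peaks, and the 5 with the largest excess held a small part of the 4835. On chromosome 4 at 49 to 50 Mb there were 40 control-only and 0 knockout-only peaks. Chromosome 10 at 42 to 43 Mb held 20 against 3, chromosome 2 at 92 to 93 Mb 14 against 2, and chromosome 11 at 51 to 52 Mb 6 against 0. In the control the median background of these 4 windows was 10.9, 11.9, 29.7 and 17.8 times the floor, and their median fold was between 2.14 and 2.71. Each of the 4 held an edge of the longest stretch without a peak in either list on its chromosome. High background there was not separated from a difference in methylation. Chromosome 3 at 183 to 184 Mb held 14 against 6, with a background of 1.32 times the floor, and lay in the same distal stretch of chromosome 3. Across whole chromosomes, the control-only share was highest on chromosome 2 among the autosomes, at 5.74%, and lowest on chromosome 19 at 1.89%.

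Where a region was methylated in both genotypes, its level relative to the library mean differed little. Scaling by the floors removes a change common to the whole genome, which therefore could not be seen. Among 206556 pairs of peaks the median depth-scaled log2 ratio of pileup, knockout over control, was 0.04 (0.03 to 0.04), with quartiles of -0.18 and 0.26. The SD of the ratios was 0.34, and 0.38 in a simulation with counting error alone. Pairs over 2-fold higher than the median in the knockout numbered 774 and those over 2-fold lower 413, against 1727 and 846 in the simulation. Differences over 4-fold were found in 6 pairs, all higher in the knockout. Pairs hold only regions that passed the caller in both libraries, which narrows their spread.

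**Figure D3:**
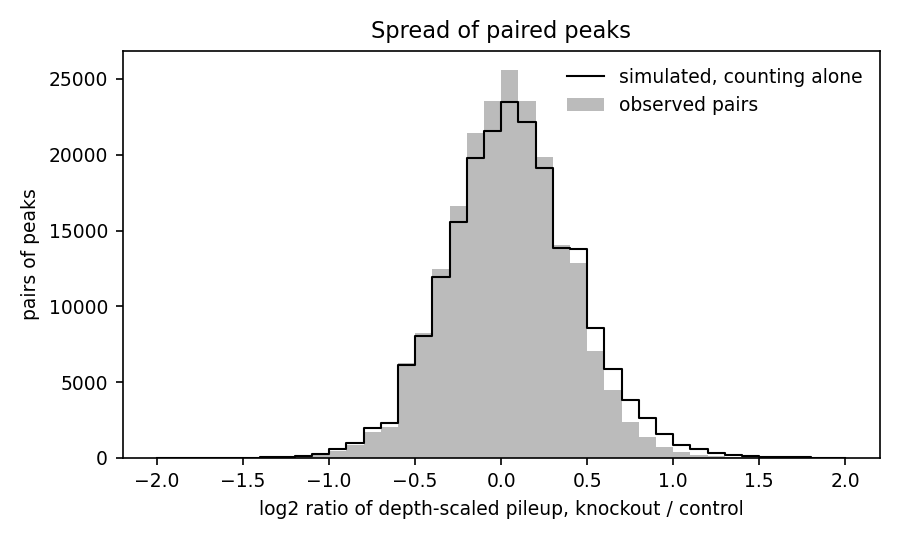
Number of paired peaks by log2 ratio of depth-scaled pileup, knockout over control, observed (bars) and simulated with counting error alone (line). The observed SD of 0.34 lay below the simulated 0.38.

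Along the chromosomes the paired regions shifted in long blocks, the clearest of them on distal chromosome 3. From 169.9 Mb (bootstrap interval 169.8 to 170.0) to the last pair, a stretch of 28.0 Mb, the median log2 ratio was -0.21 (-0.23 to -0.20) over 3332 pairs. On the rest of chromosome 3 it was 0.10 (0.09 to 0.11) over 9693 pairs. The difference was -0.31 (-0.33 to -0.30), or 0.805-fold, and 74.3% of distal pairs lay below 0 against 37.4% of the others. The local background was lower in the same stretch, with a mean log2 ratio of -0.11 (SD 0.37) against 0.14 (SD 0.37) elsewhere on the chromosome. Of the strong knockout peaks 8.97% (8.02 to 10.0) were knockout-only in the distal stretch and 19.3% (18.6 to 20.1) on the rest. The corresponding control-only shares were 4.63% (3.87 to 5.49) and 2.95% (2.56 to 3.39). Among the pairs with a background above the floor in both lists the mean log2 ratio of background was -0.06 over 2190 distal pairs and 0.17 over 5760 others. Against the stretch of equal length just before the step, where the median was 0.07 (0.05 to 0.09) over 1278 pairs, the difference was -0.28, and the background differed by -0.21 (SE 0.01). The stretch was chosen from these data, which its intervals do not allow for.

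On 9 of 23 chromosomes the fitted change point reduced the squared error more than in any of 100 permutations of blocks of 50 pairs. These were chromosomes 3, 1, 2, 16, 15, 6, 18, 5 and 7, in falling order. Over all pairs of the genome the median log2 ratio of pileup was 0.04 and the mean log2 ratio of background 0.11. The values below are to be read against these rather than against 0. On chromosome 1 the median was 0.04 before 85.7 Mb and -0.07 after it, and the mean local background was 0.12 before and 0.01 after. On chromosome 2 the median was -0.16 before 95.8 Mb and -0.04 after it, with backgrounds of -0.01 and 0.06. On chromosome 16 it was 0.06 before 53.1 Mb and 0.17 after it, with backgrounds of 0.15 and 0.24. On chromosome 15 the median was 0.05 before 77.3 Mb and -0.04 after it, with backgrounds of 0.11 and 0.05. On chromosome 18 it was -0.06 before 10.7 Mb and 0.05 after it, with backgrounds of 0.02 and 0.11. On chromosome 6 it was 0.07 before 82.9 Mb and 0.01 after it, with backgrounds of 0.13 and 0.07. The background did not move with the pileup on chromosome 5, where the median went from 0.13 to 0.08 at 112.4 Mb with backgrounds of 0.14 on both sides, or on chromosome 7, where it went from 0.08 to 0.02 at 151.3 Mb with backgrounds of 0.17 and 0.16. The change point on chromosome 3 reduced the summed squared error of the log2 ratios by 232, against 54.1 on chromosome 1, 42.6 on chromosome 2 and 30.4 on chromosome 16. Over 581 bins of 5 Mb the ratio had an SD of 0.08, from -0.26 on X at 60 Mb to 0.20 on chromosome 16 at 65 Mb.

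**Figure D4:**
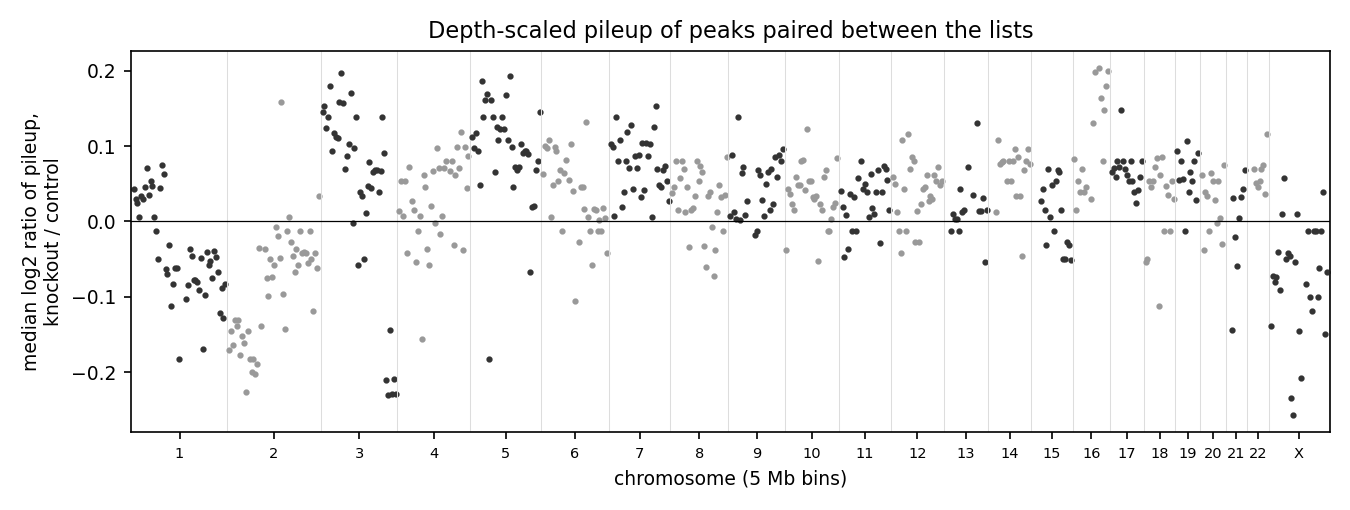
Median log2 ratio of depth-scaled pileup, knockout over control, of paired peaks in 5 Mb bins along each chromosome (1 point per bin with at least 30 pairs, shades alternating by chromosome). Values ran from -0.26 to 0.20, and distal chromosome 3 and the first part of chromosome 2 lay below 0.

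**Figure D5:**
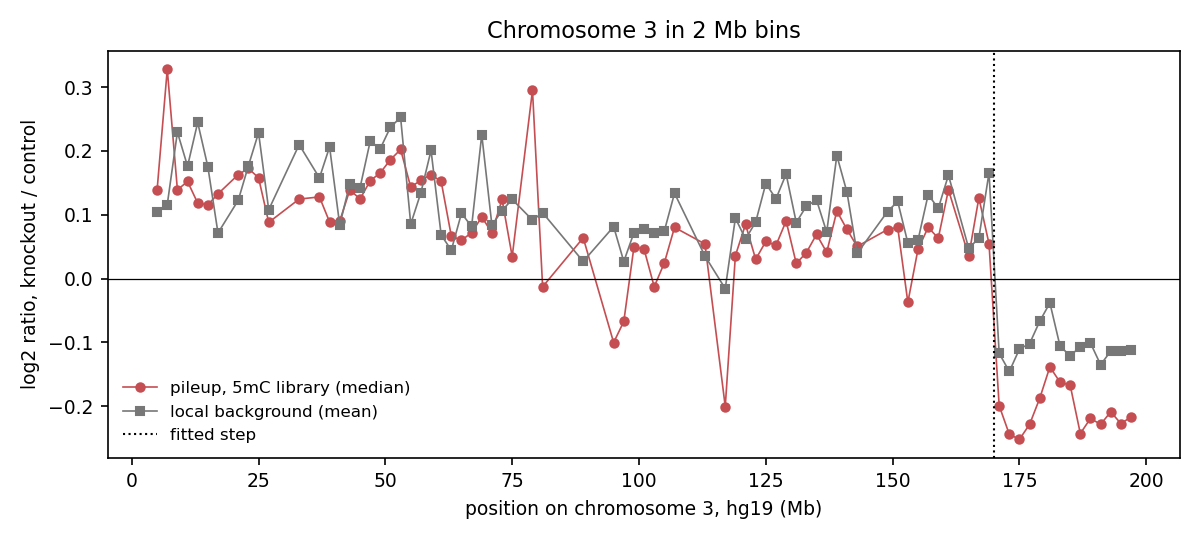
Log2 ratio, knockout over control, along chromosome 3 (Mb, hg19), for the pileup of paired peaks (circles, median per bin) and for the local background (squares, mean per bin), with the fitted step at 169.9 Mb (dotted). Beyond the step the pileup had a median of -0.21 and the background a mean of -0.11, against 0.07 and 0.10 in the stretch of equal length just before it.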

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

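Thinning to equal depth, leaving out chromosomes 2 and 3 or high background, and every alternative for the peaks at a −log10 q of 20 and for distal chromosome 3 were chosen after the results were seen. The other alternatives were fixed before the data were examined. Counts and lengths were held to 1.5 times, and ratios and log2 values to their 95% intervals. Of 65 alternatives over 13 results, 42 stayed within these bounds, 23 left them and 0 reversed. Counts and lengths are positive and could not reverse, so only the ratios and log2 values could. Some alternatives could not move. Merging overlapping peaks into regions left list-only strong peaks at 4835 and 32804 and their ratio at 6.78 by construction. Equal numbers of peaks left the 32804 knockout-only peaks by construction, since only weaker knockout peaks were dropped. These are counted among the 42. The ratio of knockout-only to control-only strong peaks was above 1 in all 10 of its alternatives. Among these, only thinning removed the difference in depth between the immunoprecipitates. With at least 50% reciprocal overlap, control-only strong peaks numbered 17183 and the ratio was 2.79. With no peak of the other list within 1000 bp, 3086 control-only and 21367 knockout-only peaks were left, and 372.5 knockout-only peaks in the depth-matched comparison at a −log10 q of 20. With strong peaks defined at a −log10 q of 5, the counts were 26384 and 66851 and the ratio 2.53. Defined by a fold of at least 8, they were 46 and 583, a ratio of 12.7. At equal numbers of peaks control-only strong peaks numbered 7870 and the ratio was 4.17, and with the immunoprecipitates matched in depth the counts were 8580 and 11471 and the ratio 1.34. Without chromosomes 2 and 3 the ratio was 7.14. The depth-matched comparison changed both the depth and the number of peaks, so its ratio cannot be put down to thinning alone. The cause was not tested for the other alternatives. With a fold of at least 5 the lists shrank by construction to 161178 control and 169894 knockout peaks, of which 123386 and 121288 were shared. Centring on the median of the pairs sets their median log2 ratio to 0 by construction. Distal chromosome 3 differed from the rest by -0.31 with either other set of pairs, and by -0.28 from the stretch of equal length just before it.

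Planned results on promoters and gene lists, and their alternatives, were not run, since no annotation of the build was used here. No paired analysis was possible because each group held 1 library. A peak missing from a list passed no threshold in that library, which does not show a region without methylation. Depth differed between immunoprecipitates and between inputs, and only the former were matched.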

Other observations

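The tests for depth in the peak counts, for distal chromosome 3 and for runs of peaks in the deposited lists were chosen after the results were seen. Those for stronger enrichment, for gained copies and for depth in the runs were chosen before.

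With the immunoprecipitates matched in depth, the knockout-only peaks with a −log10 q of at least 20 lay on 24 chromosomes. In 1 draw there were 699 of them, with a median length of 561 bp against 736 bp for all knockout peaks of that strength. Their median pileup was 14.9 times the library mean. Chromosome 6 held 52 of them, 2.38% of its knockout peaks of that strength, X held 7 (2.35%), chromosome 4 held 26 (2.14%) and chromosome 2 held 37 (1.88%). The lowest shares were on chromosome 21 with 1 (0.182%) and chromosome 16 with 19 (0.646%), leaving out Y with 6 such peaks in all. The draw also had 200 control-only peaks, of which 59 had a background above 5 times the floor, against 10 of the knockout-only ones.

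The greater number of strong peaks found in the knockout only may come in part from depth. Matching the immunoprecipitates lowered the ratio at a −log10 q of 10 from 6.78 to 1.34. That was still above the 0.763 of the no-change simulation, which held counting error only. The matching also shortened the knockout list to the control's number of peaks, and equal numbers without thinning gave a ratio of 4.17. At a −log10 q of 20 matching lowered the ratio from 31.9 to 3.55, which argues against the depth of the immunoprecipitate as the whole cause there. Thinning until both lists held as many such peaks left 2.83 (2.63 to 3.02 over draws). This step kept 63.1% of the knockout depth, against 66.1% in depth matching, and it scaled the backgrounds alike. Pileup relative to background was thus kept, so the step cannot decide on uniformly stronger enrichment. Among 206556 pairs the median pileup, scaled by the floors, was only 1.03 times as high in the knockout as in the control. Depth-matched knockout peaks at a −log10 q of 20 were yet more numerous than control ones, 53541 against 48307, so the pairs do not settle it. Knockout-only peaks did not gather where the 5 Mb pileup ratio was raised. The 5 Mb log2 pileup ratio around the depth-matched knockout-only peaks exceeded that around all knockout peaks by only 0.01 (0.00505). The highest ratio of any 5 Mb bin was 0.20 and the median bin had 0.04. The larger difference set beforehand as the sign of gained copies was thus out of reach, and the test cannot decide on them. A median over 5 Mb cannot show gained copies of shorter stretches. Gains of methylation at separate regions in the knockout cells and uniformly stronger enrichment stay open. So do gained copies, the deeper control input, GC bias and variation between cultures, untested with 1 library per group.

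Distal chromosome 3 may be present in fewer copies in the knockout cells than in the control cells, relative to the rest of the chromosome. The local background differed between the stretch and the rest by -0.25 (SE 0.01) over all pairs, and by -0.23 (SE 0.01) over pairs above the floor in both lists, whose background comes from the input. The same value of -0.25 argues against lower methylation at an unchanged number of copies as the whole cause. PRKCI, the edited gene, is on the long arm of chromosome 3, and whether the step at 169.9 Mb is a break at that gene or arose apart from the edit cannot be told apart, because the gene's position in this build was not used here.

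Peaks found in 1 list only came in runs in both genotypes. In the deposited lists there were 45 runs of at least 8 consecutive knockout-only peaks, against a highest count of 13 in 100 permutations, and 12 runs of control-only peaks against a highest of 1. With the immunoprecipitates matched, the means over 5 draws were 27.6 for the knockout (permutations at most 6) and 25.8 for the control (at most 5), a difference that was not tested. The depth of the immunoprecipitates is thus argued against as the source of the runs themselves. The part of depth in the knockout's larger number stays open. In the deposited lists the 5 longest control-only runs had backgrounds of 3.30 to 33.9 times the floor. The 5 longest knockout-only runs had 1 to 1.06 times. Neighbouring regions may differ together in either list. The high background of control runs, the unmatched inputs and local differences in GC content or coverage between the libraries were not tested as sources.

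The longest knockout-only runs in the deposited lists lay on chromosome 2 at 34917813 to 35655048 with 22 peaks, chromosome 8 at 52983876 to 53351523 with 19 and chromosome 12 at 16757740 to 17306917 with 16. Their median pileups were 24.5, 28 and 29.5, below the list's median of 36.

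The longest control-only run, on chromosome 10 at 42374408 to 42599930, held 24 peaks with a median background of 20.6 times the floor. The next, of 19 peaks on Y at 28724250 to 58912494, had a background of 3.30 times the floor. It spanned the longest stretch of Y without a peak in either list, from 28.8 to 58.8 Mb. On chromosome 2 at 92263493 to 92325804 a run of 18 control-only peaks had a background of 33.9 times the floor, and on chromosome 4 at 49135178 to 49157769 a run of 17 had 10.2 times. The mitochondrial genome held 7 control peaks with pileups of 305 to 324 and folds of 1.44 to 1.57, and 0 knockout peaks.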
